A study of Caenorhabditis elegans with 104 samples.

How the data were processed

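The labels describe wild-type N2 worms from a 2-hour timed egg lay, raised at 20 °C on 7 plates of 100 worms with bacteria. At each age 20 worms were picked at random, filmed on plates without bacteria and frozen singly. RNA of each worm went through 2 rounds of linear amplification, and samples that failed quality control were discarded, per the labels' protocols. All worms were labelled with Cy5 and the pool of 15 worms aged 4 days with Cy3, so no dye swap separates dye from sample, and a dye effect of a probe is the same at every age.

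The deposited values are log ratios, 1 per probe and array, read here as log2 ratios, in 2 tables that were identical in all values (largest difference 0). The scale and the direction, red over green, are those that limma gives by default and are not stated in the sources used here. limma is named in the submitters' processing notes with no version. The background correction and the within-array method are not given in the sources used here. Intensities were not used here, so signal over background could not be weighed. The median absolute deviation of the deposited ratios was 0.579 to 0.601 on every array, a range so narrow that the arrays appear to have been scaled to 1 spread by the authors. Missing values made up 0.537% (12559 values) and were left missing.

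Array columns were matched to samples by the labels, and all 104 ages in the table matched. Probe names were matched to a table of RefSeq genes of the WBcel235 assembly, used for names only, after dropping the splice letter: 21382 of 22490 probes (95.073%) matched. Probes of 1 gene were averaged, which gave 18889 genes, of which 10826 had a gene name, 7091 a sequence name only and 972 no match. Of 2128 genes with several probes, 313 had at least 2 probes called over age, and in 52 of these the called probes went in opposite directions. No genome was used here, so no coordinates are given. Members of near-identical families (msp, his, hsp-16, vit, pud and nspc genes) may cross-hybridise, and their single values are uncertain.

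Before the data were examined, the groups, tests, gene lists, alternatives and the rule for named genes were fixed. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with age in days for the trend, and with age as a factor for the moderated F test, for the contrasts and for day 4 against the pool. All 104 arrays entered each fit, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of 40 gene lists, 38 had at least 3 measured genes and were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Of the remaining lists, the GATA factor list had 2 measured genes (elt-5 was not measured), and no spike-in probe was measured. The preset correlation called more lists than an estimated one, 15 against 0 over the trend, while fry, which tests whether a list's genes move on balance 1 way, called 19.

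Named genes were the 10 steepest rises and 10 steepest falls over the trend, the 10 largest rises and falls for day 24 against day 4, and 3 of each for other ages against day 4. For successive ages they were 2 of each, for each described list up to 4 members with the smallest p for the trend, and for spread the 3 largest rises and falls. The vitellogenin genes, sod-3, elt-3, elt-5, elt-6, daf-16, the hsp-16 genes, unc-54, unc-119, ges-1 and rme-2 were named throughout where measured. Genes with a sequence name only were counted and not named, and hsp-70 was added after its values were seen.

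Spread was measured per worm as the median absolute deviation of its ratios from the mean of its age, corrected for group size, and correlated with age with 100000 permutations. Per gene, the absolute deviations were fitted against age with limma. For comparisons that share worms, overlaps and covariances were set beside 100 simulations without change and 100 random partings of the shared worms. After the results were seen, the worms of days 4, 8 and 12 were also parted 100 times, with genes chosen in 1 part and scored in the other, and 100 simulations gave the second step a random direction per gene. The steps were tested on simulated data with known changes over 18889 genes. For day 24 against day 4, a change of 1 was recovered in 34.0% of changed genes and of 2 in 80.0%, and 4.2% of the calls were false. For the trend, a slope of 0.05 per day was recovered in 53.0% and of 0.1 in 92.0%. A spread changed by a factor of 0.5 in 200 genes was recovered in 1.0% of them, so few such changes could be seen if few genes changed. The adjusted threshold is less strict where more genes change, so this share does not carry over to the spread results. All 5 shifted lists were called, and 0 of 31 lists that shared no gene with them. The simulated noise was independent between genes, so this does not measure how often camera calls lists of correlated genes by chance.

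Alternatives were median centring, quantile normalization, genes measured on all arrays, single probes, array quality weights, a robust and trended variance, the other deposited table, log2 of age, leaving out day 4 or day 24, and fits on the compared groups alone. Sample numbers in the titles, in bands of 20, served as a block, since they may follow the order of processing. Alternatives chosen after seeing the data were the trend without day 8 or over days 12 to 24, and leaving out the 8 worms whose mean correlation with their own age lay more than 3 median absolute deviations below the median of that age. Further ones were quantile normalization and median centring for lists, estimated correlations for lists per age, and spread over 2723 genes with little change over age (F test p over 0.5 and means within 0.5 of 0), and spread of germline and embryo genes as a set, with worms and genes resampled 1000 times. Alternatives in background correction and within-array normalization were not run, because the tables hold ratios. Figures were drawn with matplotlib 3.10.9.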

Results

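Gene expression was measured in single wild-type (N2) Caenorhabditis elegans worms with 2-colour microarrays, 1 worm per array. The worms came from eggs laid within 2 hours and were kept at 20 °C. They were harvested at 7 ages, giving 13 worms at day 4, 17 at each of days 8, 12, 14 and 16, 14 at day 20 and 9 at day 24. Each worm's RNA, labelled with Cy5, was hybridised against a pool of 15 worms aged 4 days, labelled with Cy3. Between 9 and 464 of 22490 probes had no value on an array, and the number of arrays limits the precision. Array medians lay between -0.034 and 0.009, and the correlation of any 2 arrays over probes lay between -0.062 and 0.669, with a median of 0.272.

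Values are taken as log2 of worm over pool, the usual direction of red over green, which is not stated for these tables; a reversed sign would turn every direction given here. Each age was 1 harvest of 1 cohort, so age and the day of harvest and filming cannot be told apart. The worms were individuals, so p-values measure the spread between worms of that cohort. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 from limma over 18889 genes.

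The comparison of day 4 worms with the pool of the same age gives the ratios found without a difference in age. The heat shock genes hsp-16.2, hsp-16.41 and hsp-17 had the highest ratios of all genes, at 6.74 ± 0.41, 6.31 ± 0.38 and 2.62 ± 0.31 (log2, SE, n = 13), and all 13 worms lay above the pool for each. Of 10 small heat shock protein genes, 4 were higher than the pool and 0 lower (mean 1.63, camera adjusted p = 1.13e-05, adjusted p = 0.0322 with an estimated correlation). Of 75 cytosolic ribosomal protein genes, 42 were higher and 1 lower (mean 0.60, adjusted p = 7.69e-15, adjusted p = 0.491 with an estimated correlation). Of 31 intestinal genes, 0 were higher and 12 lower (mean -0.71, adjusted p = 6.62e-06, adjusted p = 0.454 with an estimated correlation). In all, 1490 genes were higher and 1932 lower than the pool although the ages were equal, so ages are compared below through worms of each age and not through the pool.

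The slope over all 7 ages asks which transcripts rose or fell over the whole span. The steepest rise was that of numr-1, a metal-responsive nuclear protein gene, from 0.27 ± 0.99 at day 4 (SD, n = 13) to 5.60 ± 2.1 at day 24 (SD, n = 9), or 0.308 ± 0.0276 per day (log2, SE, limma adjusted p = 4.41e-16). Other steep rises were those of the tetraspanin genes tsp-1 (0.253 per day) and tsp-2 (0.241), the C-type lectin gene clec-266 (0.234), the linker histone gene his-24 (0.227), pals-32 (0.224), the RNA-directed RNA polymerase family gene rrf-2 (0.223), the homeobox gene unc-39 (0.215), the cuticle collagen gene dpy-17 (0.211) and the ABC transporter gene mrp-2 (0.207). The steepest fall was that of sysm-1, at -0.299 ± 0.0376 per day (SE, adjusted p = 2.83e-10). It was followed by the cathepsin B-like protease gene cpr-1 (-0.255), the lysozyme gene lys-7 (-0.225), the aspartyl protease gene asp-3 (-0.224), the saposin-like genes spp-1 (-0.223) and spp-5 (-0.217), dod-3 (-0.217), pud-2.2 (-0.210), the C-type lectin gene clec-47 (-0.204) and the UDP-glucuronosyltransferase gene ugt-44 (-0.199). Not all of these changed steadily: lys-7, dod-3, cpr-1, spp-1 and sysm-1 were higher at day 8 than at day 4, by 4.17, 4.11, 3.81, 2.83 and 2.78. From day 8 to day 12, sysm-1 fell by 6.68. Among the steep rises, clec-266, his-24 and unc-39 stood further above day 4 at day 12 than at day 24, as given below. Their slopes therefore do not stand for a steady rise over the whole span. In all, 2583 genes rose and 2674 fell, and 6994 had an unadjusted p under 0.05. With days 12 to 24 alone, a setting chosen after seeing the data, 1048 genes were called, of which 600 had the same direction and 19 the opposite one.

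**Figure D1:**
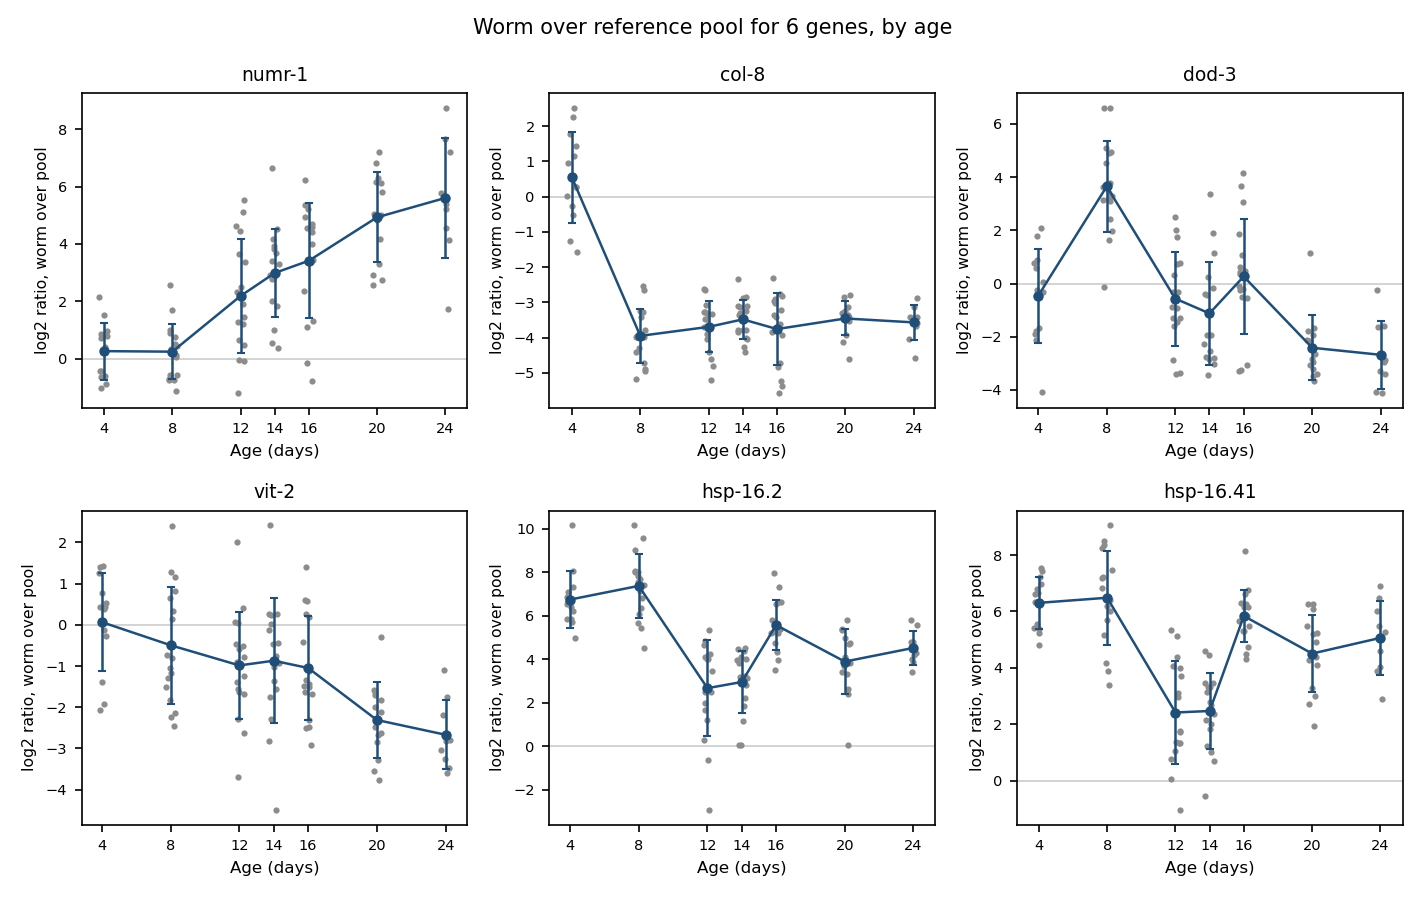
Log2 ratio of worm over pool against age in days for 6 genes, with a grey point for each worm and the mean ± SD of each age in blue. The mean of numr-1 rose from 0.27 at day 4 to 5.60 at day 24, col-8 fell from 0.55 to -3.95 by day 8, dod-3 peaked at 3.65 at day 8, and hsp-16.2 lay at 6.74 and 7.37 at days 4 and 8 against 2.68 at day 12.

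Genes of the vitellogenin, oocyte and eggshell, germline proliferation and meiosis, and intestinal lists fell more often than they rose. All 6 vitellogenin genes, which encode yolk proteins, fell with age as means over their probes (6 adjusted over the list alone, mean slope -0.0996 per day, camera adjusted p = 1.66e-07, adjusted p = 0.0916 with an estimated correlation). The slopes were -0.134 for vit-2, -0.134 for vit-6, -0.131 for vit-5, -0.0894 for vit-1, -0.0726 for vit-3 and -0.0363 for vit-4, and probes of vit-3, vit-4 and vit-5 may share targets. Of the 4 probes of vit-4, 1 fell (-0.112), and the others (0.0162, -0.0174 and -0.0325) were not called. Of 33 oocyte and eggshell genes, 3 rose and 21 fell (3 and 22 adjusted over the list alone, adjusted p = 1.92e-05, adjusted p = 0.375 with an estimated correlation), among them puf-5 (-0.0855) and cbd-1 (-0.0847). Of 31 genes of germline proliferation and meiosis, 1 rose and 20 fell (1 and 21 adjusted over the list alone, adjusted p = 4.33e-07, adjusted p = 0.282 with an estimated correlation), with fbf-2 at -0.0875 and the synaptonemal complex gene syp-2 at -0.0755. Of 31 intestinal genes, 2 rose and 16 fell (2 and 16 adjusted over the list alone, adjusted p = 1.73e-06, adjusted p = 0.282 with an estimated correlation), with spp-3 at -0.197. The gut esterase gene ges-1 fell by 0.0901 per day and the yolk receptor gene rme-2 by 0.0562. Neither the oocyte and eggshell mean nor that of germline proliferation and meiosis fell steadily. Relative to day 4, the former was 0.42 at day 8, -0.42 at day 12 and -0.33 at day 24. The latter was 0.03, -0.60 and -0.48 at these ages.

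Immune, DAF-16 target and lipid genes also fell more often than they rose. Of 47 innate immunity genes, 5 rose and 20 fell (7 and 21 adjusted over the list alone, adjusted p = 1.88e-05, adjusted p = 0.107 with an estimated correlation), with the lysozyme genes ilys-5 at -0.194, lys-1 at -0.169 and lys-2 at -0.166 per day. Of 229 C-type lectin genes, 7 rose and 38 fell (6 and 34 adjusted over the list alone, adjusted p = 0.0485, adjusted p = 0.0916 with an estimated correlation). Of 19 DAF-16 class 1 genes, which are activated by that transcription factor and of which 16 stood in another list too, 1 rose and 12 fell (1 and 13 adjusted over the list alone, adjusted p = 1.92e-05, adjusted p = 0.266 with an estimated correlation). The class 1 mean did not fall steadily: relative to day 4 it was 1.78 at day 8, -0.13 at day 12 and -0.63 at day 24. Of 14 class 2 genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, adjusted p = 0.02, adjusted p = 0.282 with an estimated correlation). Of 57 fatty acid metabolism genes, 7 rose and 18 fell (9 and 20 adjusted over the list alone, adjusted p = 0.00572, adjusted p = 0.282 with an estimated correlation), with the desaturase gene fat-7 at -0.188 and the elongase genes elo-5 at -0.174 and elo-6 at -0.134. Of 37 DNA repair genes, 3 rose and 15 fell (5 and 17 adjusted over the list alone, adjusted p = 0.0339, adjusted p = 0.582 with an estimated correlation), with hus-1 at -0.0646 and the p53 homologue gene cep-1 at -0.0483.

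Histone genes led the lists that rose over the slope. Of 27, 21 rose and 2 fell (22 and 2 adjusted over the list alone, adjusted p = 2.3e-12, adjusted p = 0.107 with an estimated correlation), with his-31 at 0.114 per day, although many histone genes are near-identical and their probes may not separate them. Of 53 neuropeptide genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 0.00784, adjusted p = 0.566 with an estimated correlation), with flp-5 at 0.139 and nlp-2 at 0.111. Of 24 insulin-like peptide genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0225, adjusted p = 0.266 with an estimated correlation), with ins-23 at 0.117. Of 30 translation factor genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0326, adjusted p = 0.32 with an estimated correlation), with eef-1A.2 at 0.149 and pab-2 at 0.110. Of 75 cytosolic ribosomal protein genes, 16 rose and 1 fell (11 and 0 adjusted over the list alone, adjusted p = 0.00335, adjusted p = 0.721 with an estimated correlation). The ribosomal slope does not stand for a rise over the whole span. The mean lay 0.93 lower at day 8 than at day 4, and for day 24 against day 4, 0 of these genes were higher and 1 was lower. The mean slope was 0.0199 per day with day 4 and 0.0596 without it. For day 24 against day 4, only the histone list of these 5 was called by camera. None of the 15 lists called with the preset correlation was called with an estimated one.

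The other lists were not called over the trend. Of the cuticle collagen genes measured, 3 rose and 27 fell (2 and 24 adjusted over the list alone, camera adjusted p = 0.0802). Without day 4, the list cuticle collagens over the age trend rose (adjusted p = 0.00118). Rises and falls numbered 7 and 11 of 42 body wall muscle genes, 9 and 1 of 48 neuronal genes, 2 and 2 of 24 pharyngeal genes and 2 and 5 of 26 hypodermal genes. They numbered 8 and 3 of 27 moulting genes, 5 and 3 of 30 zygotic embryo genes, 3 and 0 of 15 major sperm protein genes and 5 and 4 of 28 other sperm genes. The mean slope of the other sperm genes was 0.0004 per day, with a median of -0.0111, and that of 1319 chemoreceptor genes, of which 48 rose and 74 fell, was 0.0014; both means turned negative under quantile normalization, and camera's direction was down for both. Adjusted over the list alone, 0 of the 15 major sperm protein genes were called. The myosin heavy chain gene unc-54 fell by 0.0841 per day, while the integrin gene pat-2 rose by 0.0996.

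Among stress, signalling and metabolic lists that were not called, rises and falls numbered 0 and 2 of 10 small heat shock protein genes, 4 and 2 of 32 genes of HSP70, HSP90 and co-chaperones, 11 and 13 of 70 antioxidant and glutathione genes and 14 and 25 of the cytochrome P450 and UDP-glucuronosyltransferase genes. They numbered 7 and 4 of 20 genes of the insulin signalling core, 1 and 7 of 32 proteasome genes, 9 and 5 of 43 autophagy and lysosome genes and 4 and 3 of 22 apoptosis genes. They numbered 11 and 3 of 45 genes of mitochondrial electron transport and ATP synthase, 4 and 6 of 25 of the tricarboxylic acid and glyoxylate cycles and 2 and 3 of 17 of glycolysis. They numbered 4 and 10 of 38 genes of DNA replication and cell cycle, and 47 and 50 of 388 F-box and MATH-BTB genes. Single genes in them changed strongly, such as the autophagy receptor gene sqst-1 (0.168 per day), the cyclin-dependent kinase inhibitor gene cki-1 (0.185), the glutathione S-transferase genes gst-24 (0.166) and gst-6 (-0.126) and the BH3-only gene egl-1 (0.0924). The superoxide dismutase gene sod-3 had a slope of -0.0025 ± 0.0169 (SE, adjusted p = 0.938). Of the GATA factor genes linked to ageing, elt-3 had 0.019 (adjusted p = 0.084) and elt-6 0.0207 (adjusted p = 0.21, and 0.0358 with array weights). The slope of daf-16 was 0.0175 (adjusted p = 0.0475, and 0.108 with array weights), with 1 of its 7 probes called.

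**Figure D2:**
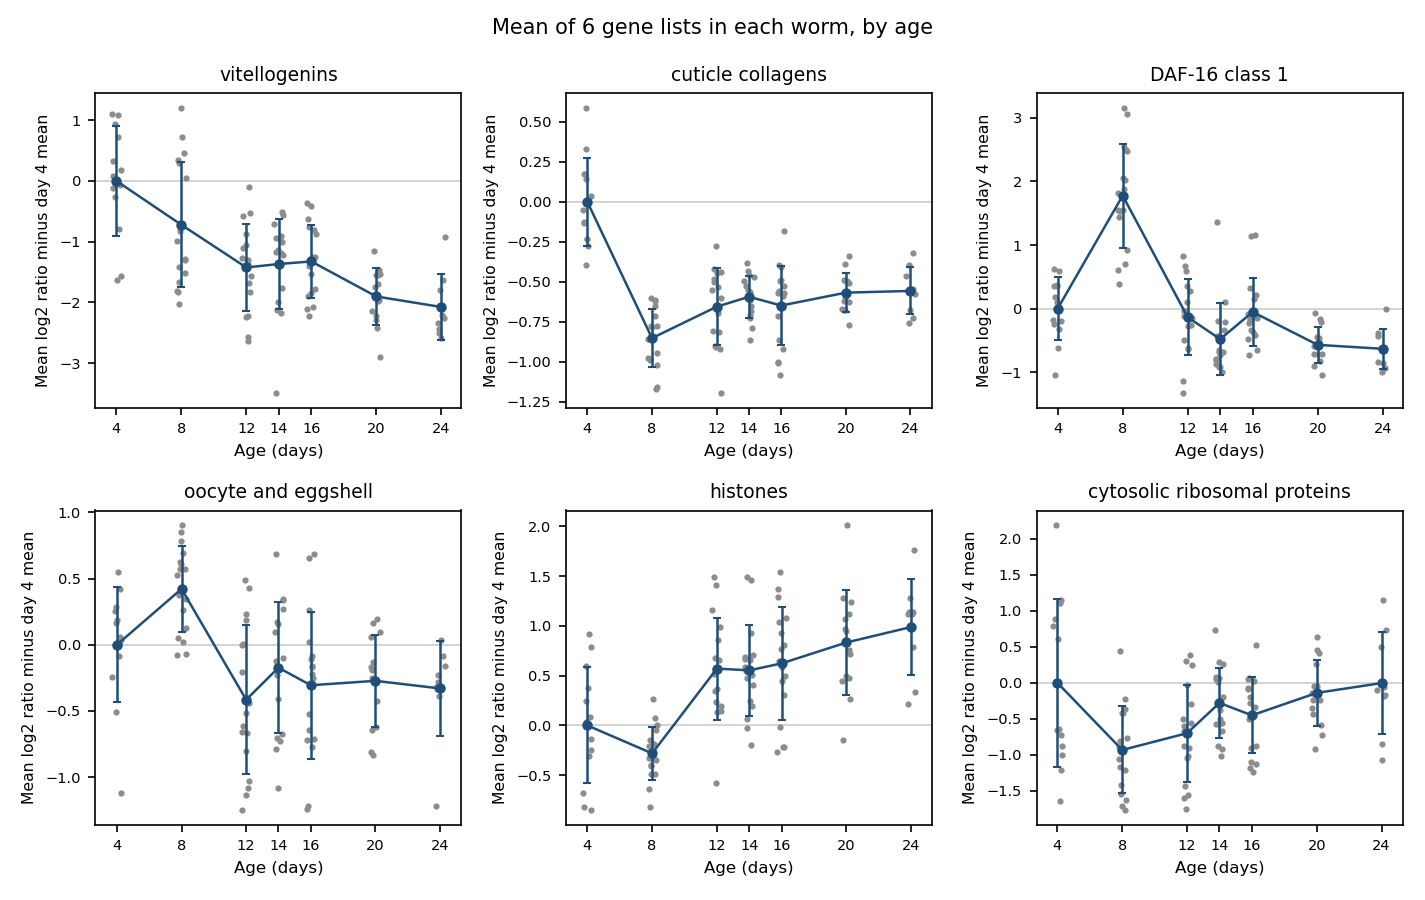
Mean log2 ratio over the genes of 6 lists in each worm, minus the mean of day 4, against age in days, with a grey point for each worm and the mean ± SD of each age in blue. The DAF-16 class 1 mean reached 1.78 at day 8, the collagen mean lay at -0.85 at day 8, and the histone mean reached 0.99 at day 24.

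A test for any difference among the 7 ages called 6242 genes with limma's moderated F (7815 at an unadjusted p under 0.05), more than the 5257 with a trend. The means of hsp-70, named here after its values were seen, were 1.82 ± 1.22, 6.01 ± 1.59, 1.68 ± 1.21, 1.65 ± 1.07, 3.96 ± 1.11, 3.14 ± 1.24 and 2.78 ± 1.5 at the 7 ages in order (SD, n as above). Its F test had an adjusted p of 5.36e-16, against 0.662 for its slope.

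Day 24 against day 4 sets the oldest worms against the youngest. The genes higher at day 24 were led by clec-266 (5.45 ± 0.66, SE, limma adjusted p = 3.7e-10, n = 9 and 13), numr-1 (5.34 ± 0.70), his-24 (4.50 ± 0.62), the caveolin gene cav-1 (4.13 ± 0.60), unc-39 (4.12 ± 0.63), dpy-17 (4.06 ± 0.60), the chitinase gene cht-1 (3.93 ± 0.64), tsp-2 (3.84 ± 0.66), rrf-2 (3.75 ± 0.41) and pals-32 (3.67 ± 0.80). Those lower were led by pud-2.2 (-5.67 ± 0.54), pud-2.1 (-4.67 ± 0.47), pud-4 (-4.41 ± 0.52), fat-7 (-4.38 ± 0.43), the collagen gene col-8 (-4.11 ± 0.35), clec-47 (-4.07 ± 0.55), ugt-44 (-4.06 ± 0.56), the methionine sulfoxide reductase gene msra-1 (-3.84 ± 0.37), sysm-1 (-3.61 ± 0.57) and the glucosylceramidase-like gene gba-4 (-3.61 ± 0.56). The near-identical pud-2.1 and pud-2.2 may share signal. In all, 1577 genes were higher and 1538 lower, 1114 and 828 of them by at least 2 times, and 5225 had an unadjusted p under 0.05.

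Between days 4 and 24, all 6 vitellogenin genes fell (6 adjusted over the list alone, mean -2.07, camera adjusted p = 7.37e-09, adjusted p = 0.0424 with an estimated correlation), with vit-2 at -2.73 ± 0.54, vit-1 at -2.72 ± 0.44 and vit-6 at -2.42 ± 0.48 (SE). Of the collagen genes, 0 rose and 37 fell (0 and 38 adjusted over the list alone, mean -0.55, adjusted p = 5.35e-07, adjusted p = 0.0424 with an estimated correlation). Of 27 histone genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone, mean 0.99, adjusted p = 4.55e-09, adjusted p = 0.252 with an estimated correlation). Of 31 intestinal genes, 1 rose and 14 fell (3 and 17 adjusted over the list alone, mean -1.16, adjusted p = 5.35e-07, adjusted p = 0.416 with an estimated correlation), and the intestinal list also lay below the pool at day 4. Of 47 innate immunity genes, 1 rose and 16 fell (1 and 18 adjusted over the list alone, adjusted p = 6.69e-05, adjusted p = 0.161 with an estimated correlation).

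Day 8 against day 4 spans the first step in age. The genes scl-2 (6.20 ± 0.61, SE, limma adjusted p = 3.1e-14, n = 17 and 13), dod-6 (5.13 ± 0.42) and the lipase gene lipl-2 (5.10 ± 0.49) rose most, and pud-2.2 (-5.56 ± 0.46), the collagen gene col-160 (-5.19 ± 0.41) and pud-2.1 (-4.91 ± 0.40) fell most. Of the collagen genes, 2 rose and 45 fell (3 and 51 adjusted over the list alone, mean -0.85, camera adjusted p = 2.51e-22, adjusted p = 3.19e-06 with an estimated correlation), with col-8 at -4.49 ± 0.30 and col-120 at -3.26 ± 0.26. Of 19 DAF-16 class 1 genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, mean 1.78, adjusted p = 6.73e-14, adjusted p = 0.00247 with an estimated correlation), with lys-7 at 4.17 ± 0.50, dod-3 at 4.11 ± 0.64 and spp-1 at 2.83 ± 0.56. Of 75 ribosomal protein genes, 0 rose and 48 fell (0 and 64 adjusted over the list alone, mean -0.93, adjusted p = 2.94e-26, adjusted p = 0.268 with an estimated correlation), and the ribosomal mean differed widely between day 4 worms (SD 1.17, n = 13). Of 42 body wall muscle genes, 1 rose and 14 fell (4 and 17 adjusted over the list alone, adjusted p = 9.03e-05, adjusted p = 0.283 with an estimated correlation). Of 33 oocyte and eggshell genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.000281, adjusted p = 0.574 with an estimated correlation). Of the vitellogenin genes, vit-1 had fallen already (-3.09 ± 0.38), while vit-2 (-0.56 ± 0.46), vit-5 (-0.09 ± 0.34) and vit-6 (-0.06 ± 0.41) did not pass. In all, for day 8 against day 4, 984 genes rose and 1160 fell, and a fit on these 2 groups alone called 1227. The main fit shares its error over all ages, while the spread between worms was higher at days 4 and 8 than later.

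Day 12 against day 8 showed the next large step. The steepest fall was that of sysm-1 (-6.68 ± 0.45, SE, limma adjusted p = 7.9e-23, n = 17 and 17), followed by hsp-16.2 (-4.70 ± 0.51), and the steepest rises were those of unc-39 (4.04 ± 0.50) and his-24 (3.74 ± 0.49). Of 19 DAF-16 class 1 genes, 0 rose and 14 fell (0 and 15 adjusted over the list alone, mean -1.91, camera adjusted p = 3.54e-18, adjusted p = 0.000416 with an estimated correlation), with dod-3 at -4.22 ± 0.60 and lys-7 at -3.75 ± 0.47. Of 47 innate immunity genes, 1 rose and 16 fell (1 and 16 adjusted over the list alone, mean -0.78, adjusted p = 2.49e-08, adjusted p = 0.0317 with an estimated correlation). Of 33 oocyte and eggshell genes, 0 rose and 23 fell (0 and 26 adjusted over the list alone, mean -0.84, adjusted p = 8.06e-15, adjusted p = 0.0703 with an estimated correlation), with puf-5 at -1.78 ± 0.28. Of 31 genes of germline proliferation and meiosis, 0 rose and 15 fell (0 and 21 adjusted over the list alone, adjusted p = 3.57e-11, adjusted p = 0.13 with an estimated correlation). Of 27 histone genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone, mean 0.85, adjusted p = 1.12e-11, adjusted p = 0.116 with an estimated correlation). In all, 1466 genes rose and 1479 fell, and 5275 had an unadjusted p under 0.05.

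The steps from day 4 to day 8 and from day 8 to day 12 were called together for 573 genes, against 334.3 if the steps were independent. Of these, 260 rose and then fell, 159 fell and then rose, and 154 moved the same way in both. The steps share the day 8 worms, which alone makes them oppose each other. The correlation across genes, which are not independent replicates, was -0.261, against a median of -0.468 over 100 simulations without change and -0.0946 (range -0.196 to 0.0201) when different day 8 worms entered the steps. The covariance was -0.0871, against -0.0474 without change and -0.0363 with the worms parted. With the worms parted, a median of 108.5 genes (lowest 85) rose and then fell, against 26.8 if independent, and a median of 34 fell and then rose, against 31. The 260 genes were chosen in these same worms for rising and then falling, so a day 8 peak in their mean follows from the choice. Their mean was -0.37 ± 0.28 at day 4 (SD, n = 13), 1.09 ± 0.42 at day 8 (n = 17), -0.33 ± 0.31 at day 12 (n = 17) and -0.63 ± 0.14 at day 24 (n = 9). The heat shock gene hsp-70, named after its values were seen, lay at 1.82 ± 1.22, 6.01 ± 1.59 and 1.68 ± 1.21 at days 4, 8 and 12 (SD).

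The changes between day 4 and the middle ages resembled each other in size. At days 12, 14, 16 and 20, clec-266 stood 6.16 ± 0.56, 5.43 ± 0.56, 5.43 ± 0.56 and 5.42 ± 0.58 above day 4 (SE). At day 12, unc-39 (5.16 ± 0.54) and his-24 (5.41 ± 0.52) were among the highest, as they were at day 14 (4.63 and 4.53), with unc-39 (4.30) and cht-1 (4.29) at day 16 and pals-32 (4.91) and tsp-2 (4.78) at day 20. The lowest were pud-2.2 (-5.21, -5.20, -5.57 and -5.76 in turn), fat-7 (-4.87, -4.86, -4.72 and -4.33) and pud-2.1 (-4.65, -4.56, -4.75 and -4.81). Collagen genes fell in number by 44, 42, 41 and 38 (45, 46, 46 and 38 adjusted over the list alone), with camera adjusted p of 1.98e-10, 1.85e-09, 8.18e-11 and 2.29e-07. The adjusted p with an estimated correlation was 0.00596, 0.00947, 0.00373 and 0.052. Genes called with limma numbered 2166 higher and 2125 lower at day 12, 1982 and 1820 at day 14, 1926 and 1868 at day 16, and 1885 and 1991 at day 20. The changes at days 12 and 24, which share the day 4 worms, had 1068 higher and 1170 lower genes in common, against 180.8 and 173.0 if independent, 0 in the median of simulations without change and 505 and 575 in the median when different day 4 worms entered each. Without change almost no gene is called, so the 0 follows from the setting. The partings leave fewer day 4 worms in each comparison, which also lowers the counts. These counts thus do not measure the part due to sharing. The covariance of the changes at days 12 and 24 was 0.416, against 0.0572 without change and 0.342 with the worms parted.

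Later steps called few genes. From day 14 to day 16, hsp-16.41 (3.37 ± 0.47, SE, limma adjusted p = 2.71e-06), hsp-16.2 (2.61 ± 0.51, adjusted p = 0.00942) and hsp-70 (2.31 ± 0.43, adjusted p = 0.00506, named after its values were seen) rose, and no other gene was called (n = 17 and 17, 788 at an unadjusted p under 0.05). Without worms that correlated weakly with their own age, only hsp-16.41 was called, and neither hsp-16.2 (adjusted p = 0.105) nor hsp-70 was. Of 10 small heat shock protein genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, mean 0.81, camera adjusted p = 1.32e-06, adjusted p = 0.00762 with an estimated correlation). For day 20 against day 16, 27 genes rose and 21 fell, but the larger direction depended on the setting. Rises made up 56.3% here, 29.3% of 140 calls with array weights, 23.8% of 63 without weakly correlated worms and 37.2% of 43 in a fit on these 2 groups. Among the 48 genes, nspe-1 (2.65 ± 0.62, adjusted p = 0.0338) and the neuropeptide gene nlp-2 (1.77 ± 0.34, adjusted p = 0.00304) rose, and scl-2 (-3.10 ± 0.60, adjusted p = 0.00304) and dod-3 (-2.68 ± 0.63, adjusted p = 0.033) fell (n = 14 and 17). The gene nspe-1 was not called without weakly correlated worms (adjusted p = 0.0902). From day 12 to day 14 and from day 20 to day 24, limma called 0 genes, with 1156 and 586 at an unadjusted p under 0.05. In simulated data, a change of 1 was recovered in 57% of genes for the former and 41% for the latter, and a change of 2 in 94% and 80%.

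The early and late changes were compared over day 8 minus day 4 and day 24 minus day 16, which share no worms. Across 18889 genes, which are not independent replicates, the correlation was -0.153, within the -0.291 to 0.252 given by 100 permutations of the age labels. The same sign was shared by 45.6% of genes, within 40.2% to 58.8%.

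The spread between worms of an age was lower at older ages, on arrays that appear to have been scaled to 1 spread. Such a scaling was not separated from a true change between worms, as described further below. The median absolute deviation of a worm's ratios from the mean of its age was 0.539 ± 0.0373 at day 4 (SD, n = 13), 0.480 ± 0.0402 at day 8, 0.457 ± 0.0528 at day 12, 0.442 ± 0.0559 at day 14, 0.455 ± 0.0723 at day 16, 0.432 ± 0.0286 at day 20 and 0.428 ± 0.0517 at day 24. Over all worms Pearson's r with age was -0.491 and Spearman's rho -0.503, each with a two-sided permutation p of 1e-05, the smallest that the permutations can give, and both stayed at 1e-05 after adjustment over the 2. Worms of days 4 and 24 all lie equally far from the median age. Without the first 2 listed of these worms r was -0.472, a setting that tests no single extreme worm. Without day 4, r was -0.283 (permutation p = 0.00662).

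Gene by gene, the absolute deviation rose with age for 39 genes and fell for 606 (limma, 3895 at an unadjusted p under 0.05). The scaling of arrays was not separated from these changes either. The largest rises were those of nit-1 (SD 0.72 at day 4 and 2.28 at day 24), rips-1 (0.61 and 1.83) and the Ro ribonucleoprotein gene rop-1 (0.32 and 1.64). The largest falls were those of nspc-9 (3.60 and 0.80), nspc-14 (3.36 and 0.37) and nspc-18 (3.13 and 0.70), which belong to 1 family of similar genes. Of 75 ribosomal protein genes, 21 fell in spread and 0 rose.

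**Figure D3:**
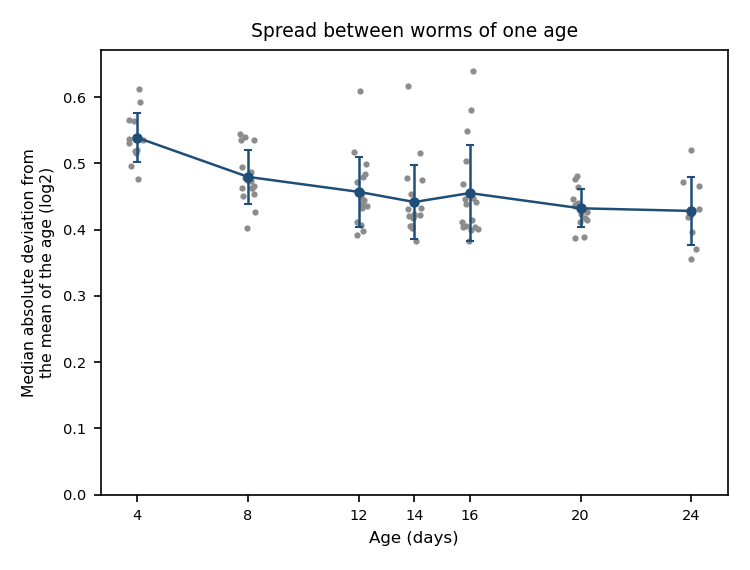
Median absolute deviation of each worm's log2 ratios from the mean of its age, against age in days, with a grey point for each worm and the mean ± SD of each age in blue. The mean was 0.539 at day 4 and 0.428 at day 24, and a scaling of arrays by the authors was not separated from this fall.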

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

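No test in this part was chosen after the results were seen. In 226 groups of 9 day 24 values (named genes and gene lists), 1 worm lay far from the other 8 in 15. Chance does this for about 1 in 20 groups, so a large part of the 15 can be chance. Values are log2 over the pool, for lists as the mean of their genes, and each is followed by the mean ± SD of the other 8 worms. Replicate 2 stood apart for cey-3 (-2.1, others -0.71 ± 0.29), atp-2 (-1.03, others -0.27 ± 0.20), cyb-2.1 (-2.38, others -0.64 ± 0.35), rme-2 (-2.37, others -0.89 ± 0.37) and the oocyte and eggshell list (-1.45, others -0.45 ± 0.14). Replicate 5, whose profile was weakly correlated with its own age, stood apart for rrf-2 (1.86, others 3.96 ± 0.45), msra-1 (-4.36, others -2.57 ± 0.43), sqt-3 (1.03, others 3.8 ± 0.34), pab-2 (0.0248, others 2.49 ± 0.47) and fbxa-153 (0.64, others 2.88 ± 0.38). Replicate 3 stood apart for pud-4 (-4.38, others -2.43 ± 0.39) and msp-56 (4.02, others 1.25 ± 0.65). Replicate 7 stood apart for vit-5 (0.0722, others -1.88 ± 0.36) and grd-3 (-1.53, others -3.27 ± 0.37), and replicate 8 for the apoptosis list (-0.18, others 0.21 ± 0.10). Genes and lists of 1 worm are not independent, and no explanation was tested for these values.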

How the results depend on the processing

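Alternatives chosen after seeing the data were the trend over days 12 to 24 or without day 8, the leaving out of weakly correlated worms, estimated correlation for lists per age, and others named in the methods. The count for the age trend was 1048 with days 12 to 24 only (fewer worms and ages), and between 3842 and 5987 under the other alternatives. The count for day 8 against day 4 was 1227 with a fit on those 2 groups, which has fewer worms and takes its error from these ages alone. The median SD of a gene between worms was 0.833 at day 4 and 0.780 at day 8, against 0.741 at day 12 and 0.659 at day 24. An error shared by all ages can therefore be too small for this comparison, and the 2 reasons were not separated. The count for day 16 against day 14 was 1 without weakly correlated worms. That for day 20 against day 16 was 140 with array weights, where 29.3% were rises, against 56.3% of 48 as reported and 23.8% of 63 without weakly correlated worms; the cause was not tested. Lists called by camera over the trend numbered 0 with an estimated correlation (6 at an unadjusted p under 0.05, and 19 by fry), and lists called over the 6 ages against day 4 numbered 7 in place of 70. An estimated correlation above the preset one widens the error of a list. The C-type lectins had a lower one over the trend (0.0051). Their unadjusted camera p went from 0.0192 to 0.00482, yet their call was lost after adjustment over the lists. The list cuticle collagens over the age trend turned to a rise without day 4 (adjusted p = 0.00118; 0.0198 under quantile normalization, as a fall). Of 1162 values of 236 named gene results under alternatives, 1147 kept their direction and side of the threshold, 12 lost their call, 3 gained one and 0 reversed. Of 266 such values of 38 lists, 232 were kept, 22 lost, 11 gained and 1 reversed.

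No other comparison count moved by over 1.5 times under the alternatives run, and median centring or quantile normalization moved the median of all genes between day 4 and day 24 from -0.0017 to 0.0020 and -0.0276. No paired analysis was possible because the labels give no replicate numbers that groups share. Alternatives in background correction and within-array normalization were not run, since the tables hold ratios, and signal over background was not used here.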

Other observations

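Tests chosen after the results were seen were the trend over days 12 to 24, estimated correlations for lists at day 12, the tests of heat shock, of handling and of dye or probe bias, the spread of genes with little change over age and of germline and embryo genes as a set, the parting of the day 8 worms, the scoring of day 8 worms left out of the choice of genes, and the ratio of genes that rose and then fell with its simulations. Over days 12 to 24 alone, 524 genes rose and 524 fell, and the genes named here were chosen after their values were seen. numr-1 rose in this span (0.297 ± 0.0525 per day, SE, limma adjusted p = 0.000141), as did the transthyretin-related gene ttr-6 (0.266 ± 0.0407), whose mean had been 0.01 at day 4 and -1.56 at day 12. hsp-16.41 had a slope of 0.235 ± 0.0514, with means of 2.48 at day 14, 5.84 at day 16 and 5.07 at day 24, against 6.31 at day 4. scl-2 fell by 0.320 per day, the aspartyl protease gene asp-1 by 0.246 and the cathepsin B-like gene cpr-1 by 0.222.

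For day 12 against day 4, camera called 17 of 38 lists with the preset correlation. With an estimated correlation it called 1, the cuticle collagens (adjusted p = 0.00596). The lists that follow are some of the 17, and none of them was called with an estimated correlation. Of 70 antioxidant and glutathione genes, 2 rose and 19 fell (2 and 19 adjusted over the list alone, camera adjusted p = 0.00357, adjusted p = 0.265 with an estimated correlation), with the glutathione S-transferase gene gst-10 at -1.2 ± 0.40 over the pool at day 12 against 0.27 ± 0.77 at day 4 (SD, n = 17 and 13). Of 43 autophagy and lysosome genes, 11 rose and 6 fell (13 and 6 adjusted over the list alone, adjusted p = 0.0194, adjusted p = 0.275 with an estimated correlation), with sqst-1 at 3.13 ± 1.05 against 0.86 ± 0.57. Of 30 zygotic embryo genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone, adjusted p = 0.0456, adjusted p = 0.265 with an estimated correlation), with ceh-51 at 1.34 ± 1.31 against 0.09 ± 1.41. Of 32 proteasome genes, 0 rose and 12 fell (1 and 12 adjusted over the list alone, adjusted p = 0.00433, adjusted p = 0.382 with an estimated correlation). The mean correlation of a worm with others of its age was 0.118 at day 4, 0.264 at day 8, 0.406 at day 12 and 0.469 at day 24. The ratios are against a pool of day 4 worms, so older worms share their change from day 4 in this measure. A higher value therefore does not show that older worms were more alike.

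The 260 genes that rose from day 4 to day 8 and fell by day 12 may mark a passing state of day 8 worms, a hypothesis found and tested on the same data. Against a few aberrant worms, 16 of 17 day 8 worms lay above every left-out day 4 and day 12 worm in over 50% of the partings in which they were themselves left out of the choice of genes, and against the order of sample numbers, 245 of the 260 were still called in both steps with the number bands as a block. With different day 8 worms in the 2 steps, the correlation across genes was -0.0946 (range -0.196 to 0.0201). Over all genes, the part played by the shared day 8 worms thus cannot be told apart. No day 8 worm was shared in these partings, yet a median of 108.5 genes (lowest 85) rose and then fell, against 26.8 if independent. This argues against sharing as the only source of the genes that rose and then fell. It does not for those that fell and then rose (a median of 34, against 31). Genes that rose and then fell numbered 3.95 times those of independent steps in the median and 1.91 times at the lowest. Simulations with no shared worms and a random direction of the second step gave 1.71 times in the median and reached 2.48 times. The median parting lay above all of these simulations, but the lowest parting lay within their range, so a preference for reversal is not settled. A heat shock in day 8 worms stays open, since hsp-70 lay 4.19 higher at day 8 than at day 4 while hsp-16.2 and hsp-16.41 differed by 0.63 and 0.18. Of 10 small heat shock protein genes, 0 rose and 1 fell from day 4 to day 8. Of 32 genes of HSP70, HSP90 and co-chaperones, 1 rose and 5 fell. Neither list was called (camera adjusted p = 0.626 and 0.491). Age itself stays open as untested and cannot be told apart from the day of harvest.

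The lower spread between worms at older ages may come from the authors' scaling of arrays. Genes with little change over age kept 0.787 times their day 4 spread at day 24, close to 0.795 for all genes, as a scaling of whole arrays would give. The ratio differed between lists, such as 0.573 for ribosomal protein genes and 1.12 for germline proliferation and meiosis, which a scaling alone would not give. The uncertainty of these list ratios was not tested, so they do not decide the question. The germ line and embryos of young worms stay open as a source: their genes as a set kept 0.882 of their spread against 0.794 for the others, a difference of 0.0881 in the direction against this source, but with a 95% interval of -0.0676 to 0.273 over 1000 resamplings of worms and genes. The bound set beforehand, a share of falls no higher than that of other genes, was met by 1.46% against 3.22%, but within chance (Fisher's exact test, two-sided p = 0.332), and was replaced after the result was seen. A true change in the spread between worms with age was not separated from the scaling.

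Heat shock genes stood far above the pool in single worms of the same age. A heat shock response during the handling of single worms could account for this but stays open: hsp-70, from another family, was called above the pool (1.82, adjusted p = 3.22e-05), while the cytosolic chaperone genes hsp-1 (-0.12, or 5 of 13 worms above) and hsp-90 (0.41, or 11 of 13) were not (adjusted p = 0.569 and 0.0678, limma). A dye or probe bias cannot be told apart from it at day 4 without a dye swap: the hsp-16.2 means differed by 4.70 between ages, which a constant bias does not give, but such a bias with a true fall after day 8 would. The ratios of hsp-4 (0.26, adjusted p = 0.165), hsp-6 (-0.05, adjusted p = 0.949), hsp-60 (-0.29, adjusted p = 0.461), hsp-3 (0.29, adjusted p = 0.532) and hsp-12.6 (0.29, adjusted p = 0.442) were not called either. Whether the handling of the single worms and of the pool differed is not given in the sources used here.

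The worms were also split at random into groups of the same sizes, in 100 splits with the real one included. Chance could be excluded for the age trend, where only 1 split gave as many calls (5257, the highest other 11), and for any difference among the ages (1 split; 6243 in the faster fit used here, the highest other 4). The same held, with 1 split each, for days 8, 12, 14, 16, 20 and 24 against day 4 (2144, 4291, 3802, 3794, 3876 and 3115 calls). The highest others were 505, 1148, 69, 825 and 743 for days 8, 12, 14, 16 and 24, and below 505 for day 20. It held for day 12 against day 8 (2945, the highest other 9), for day 20 against day 16 (48, the highest other 1) and for spread per gene (645, the highest other 2). For day 16 against day 14, 2 splits gave at least its 3 calls, under 5 in 100, but the highest other gave 11, so the exclusion of chance is narrow. For day 14 against day 12 and day 24 against day 20, limma called 0 genes (1156 and 586 at an unadjusted p under 0.05), so all 100 splits give at least as many by construction and decide nothing, with the highest others at 4 and 7. For gene lists over the trend, 3 splits gave as many as the 15 called, also under 5 in 100, with the highest other at 17. For lists in each age against day 4, 1 split gave as many as the 70, the highest other 61. Camera with the preset correlation thus called lists on random splits as well, so the adjusted p with an estimated correlation, which called fewer lists here, is given beside it. Its calls on random splits were not counted.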
